A study of Mus musculus with 12 samples.

How the data were processed

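RNA was measured in 12 mouse libraries made from total RNA with an Illumina TruSeq RNA kit, per the labels' protocols. The deposited values are raw counts per gene symbol, whole numbers whose totals differ between libraries. Per the submitters' processing notes, which name tools without role or order, fastp 0.12.4, HISAT2 2.2.1, featureCounts 2.0.1 and the mm10 build were used. The annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Without a known strand setting, reads from overlapping genes on either strand cannot be told apart, and close paralogs can share or lose reads. The labels describe the tumoral cells and the BMDCs only as immune cells, and the extraction text in the labels speaks of another tissue, so dissociation and RNA extraction of these cells are not described here. The BMDC labels also give a time of 9 days, which was used in no test.

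The tumoral and the BMDC table each hold 32190 symbols, of which 31837 matched the RefSeq gene table of GRCm38.p6, the same assembly as mm10, from which positions were taken. All columns were mapped to samples through their names, and 0 were left unmapped. The counts of mitochondrially encoded genes were not analysed here. Of the tested symbols, 125 shared identical counts in all libraries with another symbol. They were kept, and a fit with 1 symbol of each such set was added after seeing the data. Of 276 named genes, 275 had a position and 43 overlapped another tested gene on either strand, and their values are uncertain to that extent. Among those used in the text these are Cd274, Cd34, Ciita, Cxcr5, Gpr34, Il1b, Septin1, Slc16a3, Tigit, Wfdc9 and Zbtb46.

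The 2 tables were analysed separately in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr at its default settings (minimum count 10), which left 13040 tumoral and 13072 BMDC genes holding 99.89 to 99.95% of the counts. Libraries were scaled by TMM, and glmQLFit (robust) with glmQLFTest gave 1 contrast per comparison, with Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p under 0.05. All 8 BMDC libraries entered 1 fit with a mean per group, from which came LPS against no stimulation per genotype label, genotype label per stimulation state, their interaction and the average over both states. The 4 tumoral libraries formed the other fit. The SE of a log2 fold change was its size divided by the root of the F statistic. The biological coefficient of variation was 0.278 in the tumoral and 0.138 in the BMDC fit. Top-10 genes held 5.98 to 7.59% of the counts of a library.

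Gene lists for DC subsets, other cell types and pathways were fixed before the data were examined, as were the comparisons, the tests, the alternatives and the rule for named genes. Of 38 lists, those with at least 5 tested members were tested, 35 in all. Lists of mitochondrially encoded, erythroid and epithelial tumor genes had too few tested members (0, 1 and 4 of the tumoral and 0, 0 and 3 of the BMDC genes) and were not tested. The symbols Amica1, Sept3, March1 and Lilrb3 were matched to Jaml, Septin3, Marchf1 and Pirb, and Trac, Trbc1, Ahsp and Cd58 had no match. Lists were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry, which asks whether the genes of a list move one way on balance, were run beside it. With an estimated correlation 0 lists passed in any comparison. Even for LPS in WT, where 13 lists passed at the preset correlation, its smallest adjusted p was 0.238. With 2 libraries per group this setting passed nothing, so a call lost with it does not tell weaker from stronger lists. Fry passed 16 lists for LPS in WT, 12 for the knockout label without stimulation, 12 for its average, 9 for the interaction and 0 for the others. Members were also counted with p adjusted over the list alone.

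The rule for named genes took, per comparison with calls, the 8 largest increases and the 8 largest decreases among called genes with an average log2 CPM of at least 2, with no overlap between the libraries of both groups where 2 groups were compared. Predicted or unnamed genes, pseudogenes, ribosomal protein genes and antigen receptor segments were left out. With fewer than 5 calls the 10 genes with the smallest p were named, under the same limits of level and name. Added to these were the 2 members with the smallest adjusted p in each direction of every list that passed, the nitric oxide and cGMP genes with an average log2 CPM of at least 0, and Ccr7, Zbtb46, Xcr1, Il12b and Cd274. The lists of genes called in 1 experiment were tested in the other by camera, and shared calls by Fisher's exact test.

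The steps were tested on simulated negative binomial counts drawn from the mean and dispersion of each real gene and the real library sizes. In 1 group 200 genes with an average log2 CPM above 2 were changed by 2-fold or 4-fold. For late against early, over 12715 genes, 19% of the 2-fold and 83% of the 4-fold changes were called, with 13 false calls. For LPS in WT (12841 genes) these were 87% and 97% with 13 false calls, for the knockout label under LPS (12879 genes) 73% and 94% with 6, and for LPS in the libraries labelled knockout (12860 genes) 78% and 98% with 15. Each simulated gene had 1 mean in all groups apart from these changes and varied at its fitted dispersion. Real libraries can vary more, so 0 calls in a real comparison do not show that 4-fold changes were absent. Replicates differed by more than sampling noise in every group, with a chi-square per degree of freedom of 15.3 to 93.5, and Pearson correlations of log2 CPM between them were 0.9584 to 0.9869, so none was treated as 1 library deposited again. This does not show that they came from separate samples. Genes with a count above 0 numbered 14886 to 16963 per library.

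Alternatives covered other scalings (DESeq2 size factors, upper quartile, library size alone), no filter on low counts and a filter of 10 CPM in 2 libraries, a replicate block, DESeq2 1.42.0 and limma-voom, stricter thresholds, fits of the compared libraries alone and leaving out each library in turn. With 1 library left in a group, that library is assumed to vary like the other groups. Other alternatives, among them contrasts of the libraries labelled unstimulated knockout with the LPS libraries, were added after seeing the data.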

Results

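The data are 12 mouse RNA-seq libraries in 6 groups of 2. In the first experiment, dendritic cells (DCs), the antigen-presenting cells that prime T cells, were sorted from MC38 tumors at an early stage (day 7) and at a late stage (day 14). MC38 is a mouse colon carcinoma line, and the host mice carried a TdTomato reporter of Zbtb46, a transcription factor of conventional DCs. In the second experiment, bone marrow-derived DCs (BMDCs) from wild-type (WT) mice and from mice labelled Pde5 knockout were left unstimulated or were given 200 ng/ml lipopolysaccharide (LPS), a bacterial activator of Toll-like receptor 4, for 12 h. Total counts per library ranged from 14.2 to 19.3 M in the tumoral DCs and from 16.1 to 19.7 M in the BMDCs. Enough counts for a test were held by 13040 and 13072 genes respectively. Xist was counted at most 2 times in any library and the Y-linked gene Ddx3y at least 764 times in each. The labels do not say whether the 2 libraries of a group came from separate animals or cultures, so the p-values measure only the spread between these libraries, which may be technical. Group values are means ± SD with n = 2 libraries, in CPM (counts scaled to the library total), and log2 fold changes carry their standard error (SE).

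Pde5a, which encodes the cGMP-degrading phosphodiesterase that the knockout label names, was examined first in every library. The gene lies on chromosome 3 from 122729158 to 122859374 in GRCm38 (mm10), with gene identifier 242202. It was weakly expressed, with 55 and 37 counts in the WT unstimulated libraries, 47 and 61 in the libraries labelled unstimulated knockout, 52 and 20 in the WT LPS libraries and 22 and 43 in the libraries labelled LPS knockout. The early tumoral libraries held 44 and 68 Pde5a counts and the late ones 30 and 23. Averaged over both stimulation states, the log2 fold change of knockout-labelled against WT libraries was 0.00214 (SE 0.358, edgeR adjusted p = 0.998), so the Pde5a count did not separate the genotype labels. The labels do not state which part of the gene was deleted, and a deletion that leaves most exons in place would not lower a count over the whole gene. The genotype is therefore given throughout as labelled, and every direction drawn between genotypes is one between libraries so labelled. Among 59 tested genes within 10 Mb of Pde5a, 8 (13.6%) passed in the average genotype comparison against 11.1% of 12973 genes elsewhere (Fisher's exact test, two-sided, p = 0.531).

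The comparison of late with early tumoral DCs asked how the transcriptome of these cells changed as the tumor progressed. Tested as lists at a preset correlation between genes, those of T cells and natural killer (NK) cells lay lower in the late libraries, and those of hypoxia, lysosomal and glycolytic genes lay higher. With an estimated correlation these 5 calls were lost (adjusted p = 0.435, and 0.519 for glycolysis), and fry, a test of whether the genes of a list move one way on balance, passed 0 lists. Lck, the kinase that starts T cell receptor signalling, fell from 80.0 ± 6.61 to 16.8 ± 2.28 CPM (log2 fold change -2.25, SE 0.233). Cd226, an activating receptor of T and NK cells, fell from 40.9 ± 7.08 to 5.82 ± 0.831 CPM (-2.81, SE 0.286), and Sytl2, a granule-docking protein of cytotoxic lymphocytes, fell from 26.8 ± 1.47 to 3.25 ± 0.421 CPM (-3.04, SE 0.306). These were the 3 genes that passed in edgeR, each with an adjusted p of 0.0444, and 0 genes rose. An unadjusted p under 0.05 was reached by 1438 genes, and 28 had an adjusted p under 0.06. DESeq2 called 311 genes and limma-voom 0.

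Among the next genes by p were further lymphocyte genes, although none of them passed. The inhibitory receptor Ctla4 had a log2 fold change of -2.27 (SE 0.251), the adhesion receptor Cd2 one of -2.63 (SE 0.312), Sh2d2a, a T cell adaptor, one of -2.46 (SE 0.286) and Gimap4, a GTPase of lymphocytes, one of -2.51 (SE 0.293), all with an adjusted p of 0.052. The inhibitory receptors Tigit (-2.26) and Pdcd1 (-2.06) followed with adjusted p of 0.0549 and 0.0557. Septin1 (-1.75, adjusted p = 0.0557) has the same counts in all libraries as a neighbouring gene model, so it is uncertain as a single gene.

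Of the 16 tested T cell genes, 1 was lower and 15 did not pass, and 15 were lower when adjusted over the list alone. The median log2 fold change was -2.49 (camera adjusted p = 5.59e-35, adjusted p = 0.435 with an estimated correlation). The exception was Il7r, the IL-7 receptor, at +1.02 (SE 0.643, adjusted p = 0.614). None of the 13 NK and cytotoxic genes passed alone, and 13 were lower when adjusted over the list alone. The median was -2.28 (adjusted p = 6.81e-23, adjusted p = 0.435 with an estimated correlation). Il2rb, the shared IL-2 and IL-15 receptor chain, stood at 375 ± 20.9 CPM early and 63.6 ± 32.9 CPM late (adjusted p = 0.0844). The 23 interferon-gamma response genes lay lower beside these lymphocyte genes, with 0 passing and 13 lower when adjusted over the list alone. Their median was -0.82 (adjusted p = 1.3e-12, adjusted p = 0.435 with an estimated correlation). The guanylate-binding proteins Gbp4 and Gbp7, which act against intracellular pathogens, had log2 fold changes of -1.66 and -1.65 (adjusted p = 0.113 and 0.129).

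Markers of other cell types moved as well. The 16 fibroblast genes had a median of -1.82 (adjusted p = 1.36e-11, adjusted p = 0.519 with an estimated correlation), with Sparc, a matrix protein, at 103 ± 24.0 CPM early and 35.7 ± 17.3 CPM late. The 13 endothelial genes had a median of -0.96 (adjusted p = 7.99e-05, adjusted p = 0.435 with an estimated correlation), with 2 lower when adjusted over the list alone, and the 8 mast cell and basophil genes one of -1.26 (adjusted p = 0.00901, adjusted p = 0.699 with an estimated correlation). Plasmacytoid DC genes had a median of -0.43 (16 genes, adjusted p = 0.0146, adjusted p = 0.699 with an estimated correlation), led by Lag3, a receptor that activated T cells also carry, at -1.64. In these 4 lists 0 genes passed, and beyond the 2 endothelial genes 1 plasmacytoid DC gene was lower when adjusted over the list alone. The mast cell call ended without early replicate 2 or late replicate 1 (adjusted p = 0.379 and 0.134), and the plasmacytoid call without late replicate 2 (median -0.01, adjusted p = 0.376). The 25 monocyte and macrophage genes had a median of +0.40 (0 passing, 0 when adjusted over the list alone, adjusted p = 0.00672, adjusted p = 0.435 with an estimated correlation). Within that list the phagocyte genes Trem2 (+1.14) and Cd68 (+0.82) lay opposite to the monocyte genes Ly6c2 (-1.28) and Ccr2 (-0.86).

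The lists that lay higher in late libraries were led by hypoxia. None of its 24 genes passed alone and 8 were higher when adjusted over the list alone. The median was +0.72 (adjusted p = 1.3e-12, adjusted p = 0.435 with an estimated correlation). Adm, which encodes the hypoxia-induced peptide adrenomedullin, stood at 8.85 ± 1.42 CPM early and 35.9 ± 1.79 CPM late (log2 fold change +2.02, SE 0.267, adjusted p = 0.056). Lysosome and phagocytosis genes had a median of +0.62, with 0 of 28 passing and 10 higher when adjusted over the list alone (adjusted p = 1.7e-12, adjusted p = 0.435 with an estimated correlation). Among them Atp6v0d2, a subunit of the proton pump that acidifies lysosomes, was at +2.14 (SE 0.276, adjusted p = 0.0557). Of 20 glycolysis genes 0 passed and 5 were higher when adjusted over the list alone. The median was +0.59 (adjusted p = 1.14e-06, adjusted p = 0.519 with an estimated correlation). The glucose transporter Slc2a1, a member, was at +1.25 (SE 0.308, adjusted p = 0.224). Chemokine genes had a median of +0.42 (25 genes, 2 higher when adjusted over the list alone, adjusted p = 0.000286, adjusted p = 0.699 with an estimated correlation), with Pf4, a platelet and macrophage chemokine, at +1.81 (adjusted p = 0.0565). Smaller shifts were found for genes of tissue dissociation stress (+0.49, adjusted p = 0.000993), the unfolded protein response (+0.26, adjusted p = 0.0105), oxidative phosphorylation (+0.225, adjusted p = 0.00475), lipid handling (+0.18, adjusted p = 0.017) and cholesterol synthesis (+0.175, adjusted p = 0.0331). With an estimated correlation their adjusted p was 0.699, 0.699, 0.827, 0.435 and 0.519, in that order. In these lists 0 genes passed, and 1 unfolded protein gene and 1 lipid gene were higher when adjusted over the list alone. The calls of the stress, unfolded protein and cholesterol lists ended without early replicate 1 (adjusted p = 0.157, 0.227 and 0.156), those of the unfolded protein, cholesterol and lipid lists without late replicate 1 (0.0549, 0.0871 and 0.12), and that of oxidative phosphorylation without early replicate 2 or late replicate 2 (0.147 and 0.205).

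The conventional DC identity lists did not pass. Type 1 conventional DC (cDC1) genes had a median of +0.00271 with a mean and a test direction below 0 (adjusted p = 0.718), type 2 (cDC2) genes a median of -0.21 (adjusted p = 0.133) and the core conventional DC genes one of -0.17 (adjusted p = 0.602). Ccr7, the receptor that guides mature DCs to lymph nodes, stood at 329 ± 322 CPM early and 323 ± 20 CPM late, so the 2 early libraries differed more than the stages. Zbtb46 was at 32.6 ± 18.3 and 26.3 ± 4.17 CPM, and Il12b, a subunit of the T cell-polarising cytokine IL-12, at 71.3 ± 65.7 and 41.2 ± 17.6 CPM. The count of 3 genes was 0 without late replicate 1 (Lck -2.42, adjusted p = 0.217) or late replicate 2 (Lck -2.12, adjusted p = 0.716), where its log2 fold change stayed near that with all libraries, and it was also 0 under DESeq2 size factors or a filter of 10 CPM (adjusted p of Lck 0.0555 and 0.0813), whereas 1088 passed without early replicate 1 and 565 without early replicate 2. Without early replicate 1 the chemokine list lost its call with a median of -0.02 (adjusted p = 0.128), and with the filter of 10 CPM the endothelial and cholesterol lists lost theirs (0.127 and 0.214). Upper-quartile scaling gave 15 genes higher and 30 lower and library size alone 7 higher and 21 lower, the latter moving the median of all genes by -0.107.

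**Figure D1:**
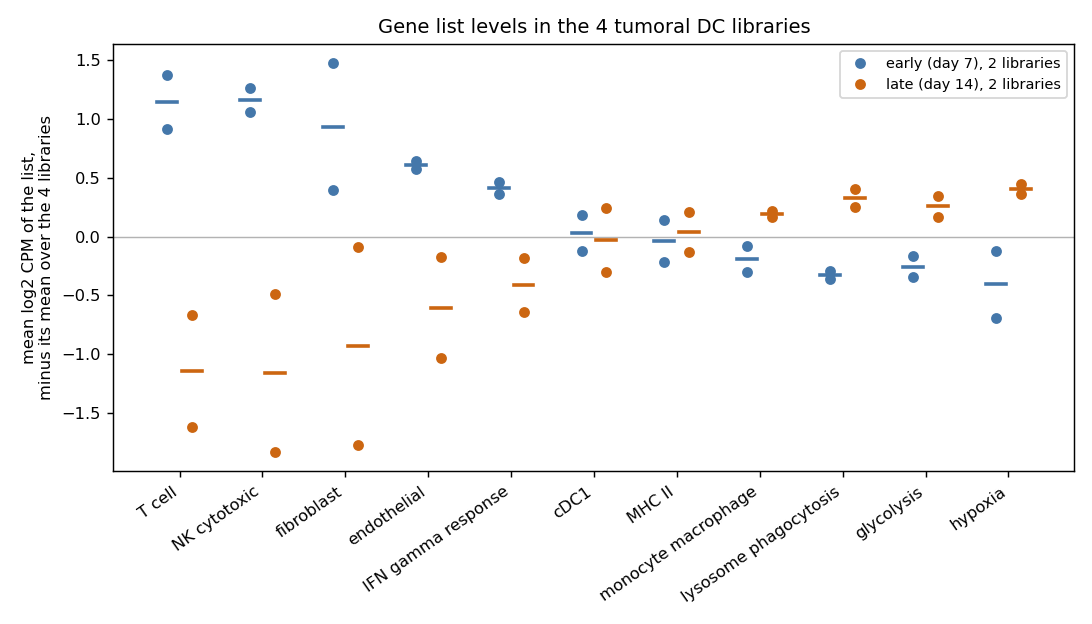
Mean log2 CPM of each of 11 gene lists in each of the 4 tumoral DC libraries, minus the list's mean over the 4 libraries; points are libraries, colored by stage, on a linear axis in log2 units. The T cell and NK points of both late libraries lie below those of both early libraries, with median log2 fold changes of -2.49 and -2.28, and the hypoxia points lie above, with +0.72.

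In WT BMDCs, LPS raised interferon-stimulated and inflammatory genes and lowered cDC1 genes. Saa3, an acute-phase protein, rose from 0.610 ± 0.465 to 89.4 ± 5.01 CPM (log2 fold change 7.17, SE 0.774, edgeR adjusted p = 0.000967), and Il1b, the cytokine IL-1 beta, rose from 39.7 ± 2.62 to 668 ± 54.4 CPM (4.07, SE 0.206, adjusted p = 0.00012). Isg15, a ubiquitin-like interferon effector, rose from 15.6 ± 4.41 to 392 ± 63.7 CPM, and Irf7, the transcription factor that amplifies type I interferon, from 24.5 ± 6.65 to 578 ± 74.1 CPM. Clec9a, the receptor with which cDC1 cells sense dead cells, fell from 43.7 ± 6.81 to 9.47 ± 2.65 CPM (-2.21, SE 0.223, adjusted p = 0.000396). In all, 4910 genes passed, 2609 higher and 2301 lower, of which 958 and 963 changed by more than 2-fold.

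The genes with the largest increases were Saa3, Slfn1 (7.09, SE 0.456), Slfn4 (6.98, SE 0.710), Gstt1 (6.96, SE 0.633), Olfr56 (6.61, SE 0.713), Ifi206 (6.51, SE 0.618), H2-Q10 (6.38, SE 0.417) and Wfdc9 (6.38, SE 0.442). Slfn1 and Slfn4 belong to the interferon-induced Schlafen family. Slfn, Ifi200 and H2-Q genes have close paralogs with which they can share reads, so single members are uncertain. The largest decreases were those of Hpgd, which degrades prostaglandins (-5.19, SE 0.848), the kinase Dmpk (-4.15, SE 0.542), Mamdc2 (-3.96, SE 0.732), Lmo1 (-3.93, SE 0.70), Hgfac (-3.84, SE 0.507), the lectin Clec10a (-3.72, SE 0.703), the lysophospholipid receptor Gpr34 (-3.66, SE 0.363) and the prostaglandin receptor Ptger3 (-3.57, SE 0.593).

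Of 35 type I interferon response genes 34 rose, 0 fell and 1 did not pass, and 35 were higher when adjusted over the list alone. Their median was +3.30 (camera adjusted p = 1.74e-49, adjusted p = 0.361 with an estimated correlation). The interferon-gamma list had 22 of 24 genes higher and 1 lower, with 22 and 1 when adjusted over the list alone. The median was +3.06 (adjusted p = 1.47e-32, adjusted p = 0.238 with an estimated correlation). Ciita, the master regulator of MHC class II, was the member that fell (-0.74). Inflammatory NF-kB genes counted 20 higher, 1 lower and 7 not passing, with 23 and 1 when adjusted over the list alone. The median was +1.21 (adjusted p = 6.13e-15, adjusted p = 0.238 with an estimated correlation). The mature, migratory DC program had 20 of 28 genes higher and 0 lower, with 22 higher when adjusted over the list alone. The median was +0.91 (adjusted p = 3.92e-10, adjusted p = 0.449 with an estimated correlation). Members of this program include Cd200, an inhibitory ligand (+1.83), and Ccr7 (+1.24, from 3130 ± 532 to 7390 ± 81.3 CPM). MHC class I genes rose in 15 of 20 cases and 0 fell, with 15 higher and 1 lower when adjusted over the list alone. The median was +0.87 (adjusted p = 9.74e-08, adjusted p = 0.361 with an estimated correlation). Checkpoint and suppressive genes counted 11 higher and 4 lower of 20, with 13 and 4 when adjusted over the list alone. The median was +1.28 (adjusted p = 0.000657, adjusted p = 0.361 with an estimated correlation). Cd274, which encodes PD-L1, rose from 218 ± 67.0 to 865 ± 87.6 CPM.

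The cDC1 list had 3 genes higher, 11 lower and 2 not passing, with 3 and 11 when adjusted over the list alone. Its median was -1.95 (adjusted p = 0.000519, adjusted p = 0.389 with an estimated correlation). Tlr3, which senses double-stranded RNA, fell (-2.03, SE 0.268), as did the chemokine receptor Xcr1 (-2.02, SE 0.407), while Irf8, a transcription factor of the lineage, rose (+0.66, SE 0.153). Neutrophil genes fell in 7 of 14 cases and 0 rose, with 8 lower when adjusted over the list alone. The median was -1.30 (adjusted p = 0.00111, adjusted p = 0.544 with an estimated correlation). The granule genes Ltf (-2.97) and Ngp (-1.98) were among those that fell. Cell cycle genes counted 1 higher, 7 lower and 22 not passing, with the same numbers of 1 and 7 when adjusted over the list alone. The median was -0.64 (adjusted p = 0.00771, adjusted p = 0.814 with an estimated correlation). Cholesterol synthesis had 1 gene higher and 11 lower of 24, with 2 and 13 when adjusted over the list alone. The median was -0.41 (adjusted p = 0.017, adjusted p = 0.814 with an estimated correlation), with Dhcr7, the last enzyme of the pathway, at -1.31 (SE 0.212). Of 12 costimulation genes 6 rose and 2 fell, also when adjusted over the list alone. The median was +0.75 (adjusted p = 0.00779, adjusted p = 0.544 with an estimated correlation). Of 20 genes of nitric oxide and cGMP signalling 7 rose and 2 fell, also when adjusted over the list alone. The median was +0.41 (adjusted p = 0.02, adjusted p = 0.361 with an estimated correlation). Of 40 actomyosin genes 18 rose and 7 fell, with 21 and 8 when adjusted over the list alone. Their median was +0.29 (adjusted p = 0.0321, adjusted p = 0.663 with an estimated correlation). The number of genes was 2926 without WT unstimulated replicate 2, 2632 without WT LPS replicate 1 and 3233 without WT LPS replicate 2. Without WT LPS replicate 1 the calls of the cell cycle and cholesterol lists and of Xcr1 and Ciita ended (adjusted p = 0.183, 0.101, 0.0514 and 0.0682), without WT LPS replicate 2 those of the actomyosin list and Irf8 (0.106 and 0.085), and without WT unstimulated replicate 2 those of the actomyosin and cholesterol lists (0.0895 and 0.0731). The actomyosin call also ended under upper-quartile scaling, library size alone and the filter of 10 CPM (0.0561, 0.133 and 0.108), and that of the nitric oxide and cGMP list without a filter (0.0813). With library size as the only scaling the median of all genes moved by -0.204 and 31.2% of the called genes were higher (1689 against 3728 lower), in place of 53.1%.

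Unstimulated libraries labelled Pde5 knockout had high levels of the genes that LPS raised in WT cells. Nos2, the inducible nitric oxide synthase on chromosome 11 (78920787 to 78960226), was at 0.417 ± 0.192 CPM in WT and 119 ± 49.7 CPM in the libraries labelled knockout (log2 fold change 8.13, SE 0.433, edgeR adjusted p = 0.000502). Saa3 rose from 0.610 ± 0.465 to 520 ± 284 CPM (9.71, SE 0.793, adjusted p = 0.00111) and Il1b from 39.7 ± 2.62 to 572 ± 168 CPM (3.85, SE 0.204, adjusted p = 0.000415). Isg15 and Irf7 rose to 216 ± 83.3 and 316 ± 99.2 CPM, and Clec9a fell to 12.7 ± 1.14 CPM (-1.78, SE 0.216, adjusted p = 0.00181). A total of 2357 genes passed, 1575 higher and 782 lower, of which 648 and 172 differed by more than 2-fold.

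After Saa3 and Nos2, the largest increases in the libraries labelled knockout were those of the formyl peptide receptor Fpr2 (6.85, SE 0.565), Olfr56 (6.70, SE 0.708), Slfn4 (6.68, SE 0.714), Slfn1 (6.35, SE 0.460), Gstt1 (6.27, SE 0.647) and Wfdc9 (6.26, SE 0.442). The largest decreases were those of Dmpk (-3.77, SE 0.523), the transcriptional inhibitors Id1 (-3.59, SE 0.894) and Id3 (-3.27, SE 0.557), the progenitor marker Cd34 (-3.29, SE 0.737), the histone deacetylase Hdac9 (-2.07, SE 0.384), Xcr1 (-2.05, SE 0.403), Dmwd (-1.89, SE 0.300) and Nqo1, an antioxidant enzyme (-1.80, SE 0.444). Id1 and Cd34 had wide spread in WT libraries, at 23.8 ± 22.8 and 99.8 ± 60.8 CPM.

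Type I interferon genes were higher in 34 of 35 cases and lower in 0, also when adjusted over the list alone. The median was +2.27 (camera adjusted p = 1.4e-45, adjusted p = 0.26 with an estimated correlation). Interferon-gamma genes counted 20 higher and 1 lower of 24, with 21 and 1 when adjusted over the list alone. The median was +2.2 (adjusted p = 3.12e-33, adjusted p = 0.212 with an estimated correlation). Of 28 inflammatory NF-kB genes 18 rose and 0 fell, with 20 and 1 when adjusted over the list alone. Their median was +0.855 (adjusted p = 2.31e-18, adjusted p = 0.212 with an estimated correlation). Mature DC genes rose in 13 of 28 cases with 0 lower, and 17 were higher when adjusted over the list alone. The median was +0.73 (adjusted p = 3.21e-07, adjusted p = 0.514 with an estimated correlation). Costimulation genes counted 7 higher and 2 lower of 12, with 8 and 2 when adjusted over the list alone. The median was +0.75 (adjusted p = 6.85e-05, adjusted p = 0.393 with an estimated correlation). Tnfsf4, which encodes OX40 ligand, rose (+2.85, SE 0.208), as did Cd86 (+1.18, SE 0.129), a ligand of CD28. Checkpoint and suppressive genes counted 10 higher and 2 lower of 20, the same when adjusted over the list alone. Their median was +0.96 (adjusted p = 6.85e-05, adjusted p = 0.26 with an estimated correlation). MHC class I genes counted 12 higher and 0 lower of 20, with 15 and 1 when adjusted over the list alone. The median was +0.46 (adjusted p = 0.000656, adjusted p = 0.514 with an estimated correlation).

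Of 20 genes of nitric oxide and cGMP signalling, the pathway in which PDE5 acts, 6 rose and 0 fell, with 11 higher when adjusted over the list alone. The median was +0.375 (adjusted p = 5.81e-05, adjusted p = 0.212 with an estimated correlation). Those that rose serve arginine and nitric oxide metabolism or make cGMP: Nos2, Arg1, which encodes arginase (+3.85, SE 0.552), the arginine transporter Slc7a2 (+2.98, SE 0.454), Npr1, a receptor that makes cGMP (+1.5, SE 0.294), Ass1 (+0.74, SE 0.147) and Gch1 (+0.64, SE 0.166). Hypoxia genes rose in 7 of 23 cases with 0 lower, and 8 were higher when adjusted over the list alone. Their median was +0.71 (adjusted p = 0.000128, adjusted p = 0.595 with an estimated correlation), with the stress-response gene Ddit4 at +2.26 (SE 0.210). The cDC1 list had 2 genes higher and 7 lower of 16, with 2 and 11 when adjusted over the list alone. The median was -1.15 (adjusted p = 0.00106, adjusted p = 0.393 with an estimated correlation). Cholesterol synthesis had 1 gene higher and 9 lower of 24, with 1 and 19 when adjusted over the list alone. The median was -0.65 (adjusted p = 7.48e-06, adjusted p = 0.595 with an estimated correlation). Cell cycle genes (30 genes, 0 higher, 1 lower, also when adjusted over the list alone, median -0.49, adjusted p = 0.0147) and unfolded protein response genes (20 genes, 1 higher, 3 lower, also when adjusted over the list alone, median -0.26, adjusted p = 0.0403) had an adjusted p of 0.691 each with an estimated correlation. The count was 576 without the library labelled unstimulated knockout replicate 1, 852 without WT unstimulated replicate 2 and 1036 in a fit of the 4 libraries alone. Without the library labelled unstimulated knockout replicate 1 the calls of Npr1, Ass1, Gch1, Id1, Id3, Cd34, Dmpk, Dmwd, Nqo1 and the cell cycle and unfolded protein lists ended (adjusted p = 0.133, 0.0998, 0.243, 0.265, 0.116, 0.229, 0.0793, 0.0538, 0.126, 0.151 and 0.12). Without WT unstimulated replicate 2 those of Ass1, Gch1, Id1, Id3, Cd34, Hdac9, Nqo1 and both lists ended (0.0607, 0.165, 0.12, 0.0501, 0.121, 0.0588, 0.146, 0.0835 and 0.151), and without the library labelled unstimulated knockout replicate 2 those of Id1 and Cd34 (0.0807 and 0.0885). The calls of Npr1, Nqo1, Id3, Cd34 and Id1 also ended without a filter (0.0787, 0.101, 0.0607, 0.122 and 0.152), that of Id1 with limma-voom (0.0926), those of Ass1, Gch1, Nqo1 and Id1 in the fit of the 4 libraries (0.0628, 0.0909, 0.0685 and 0.0569) and that of the unfolded protein list with the filter of 10 CPM (0.106). Under library size alone the median of all genes moved by -0.104 and 49.6% of called genes were higher (1282 against 1301 lower), in place of 66.8%.

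The 4910 genes that passed for LPS in WT cells gave each library a position, 0 being the mean of the WT unstimulated and 1 that of the WT LPS libraries. The libraries labelled unstimulated knockout lay at 0.832 and 0.587, the WT LPS libraries at 1.05 and 0.951 and the libraries labelled LPS knockout at 0.952 and 1.02. Across the 13072 genes, which are not independent replicates, the log2 fold changes of LPS in WT cells and of the knockout label in unstimulated cells had a Pearson correlation of 0.8697. Both comparisons use the same WT unstimulated libraries, and unchanged simulated groups set against those libraries gave 0.497 over 20 simulations. The covariance was 0.727 against a simulated 0.0566, a difference of 0.67, and 84.28% of genes had the same sign against 66.7%. Of the calls, 1459 were higher in both comparisons (simulated 0.35, independent lists 314.3) and 696 lower in both (simulated 0.05, independent lists 137.7), and 0 went opposite ways. The simulation held no effect in either comparison, so few simulated calls could be shared. It does not tell how many of the real shared calls the shared controls made. In a split chosen after seeing the data, each comparison had 1 of the 2 WT unstimulated libraries as its own control. The covariance was then 0.673 or 0.712, depending on which library went to which comparison, and the correlation 0.665 or 0.713. The same sign was found in 74.5 or 78.3% of genes. With 1 control library per comparison these values are less precise, and part of the excess in the shared calls may still come from the shared controls.

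**Figure D2:**
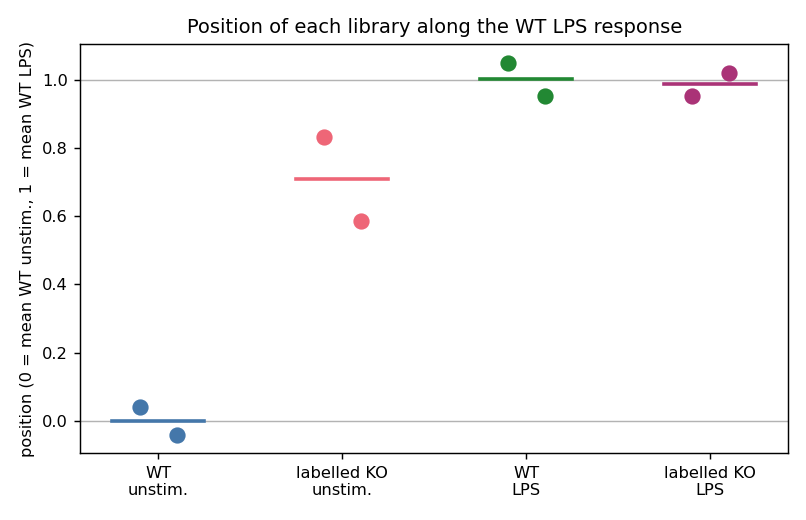
Position of each of the 8 BMDC libraries along the WT LPS response, computed over 4910 genes and without unit, with 0 at the mean of the 2 WT unstimulated libraries and 1 at the mean of the 2 WT LPS libraries; each point is a library. The libraries labelled unstimulated knockout lie at 0.832 and 0.587, nearer to the 4 LPS libraries (0.951 to 1.05) than to the WT unstimulated libraries.

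**Figure D3:**
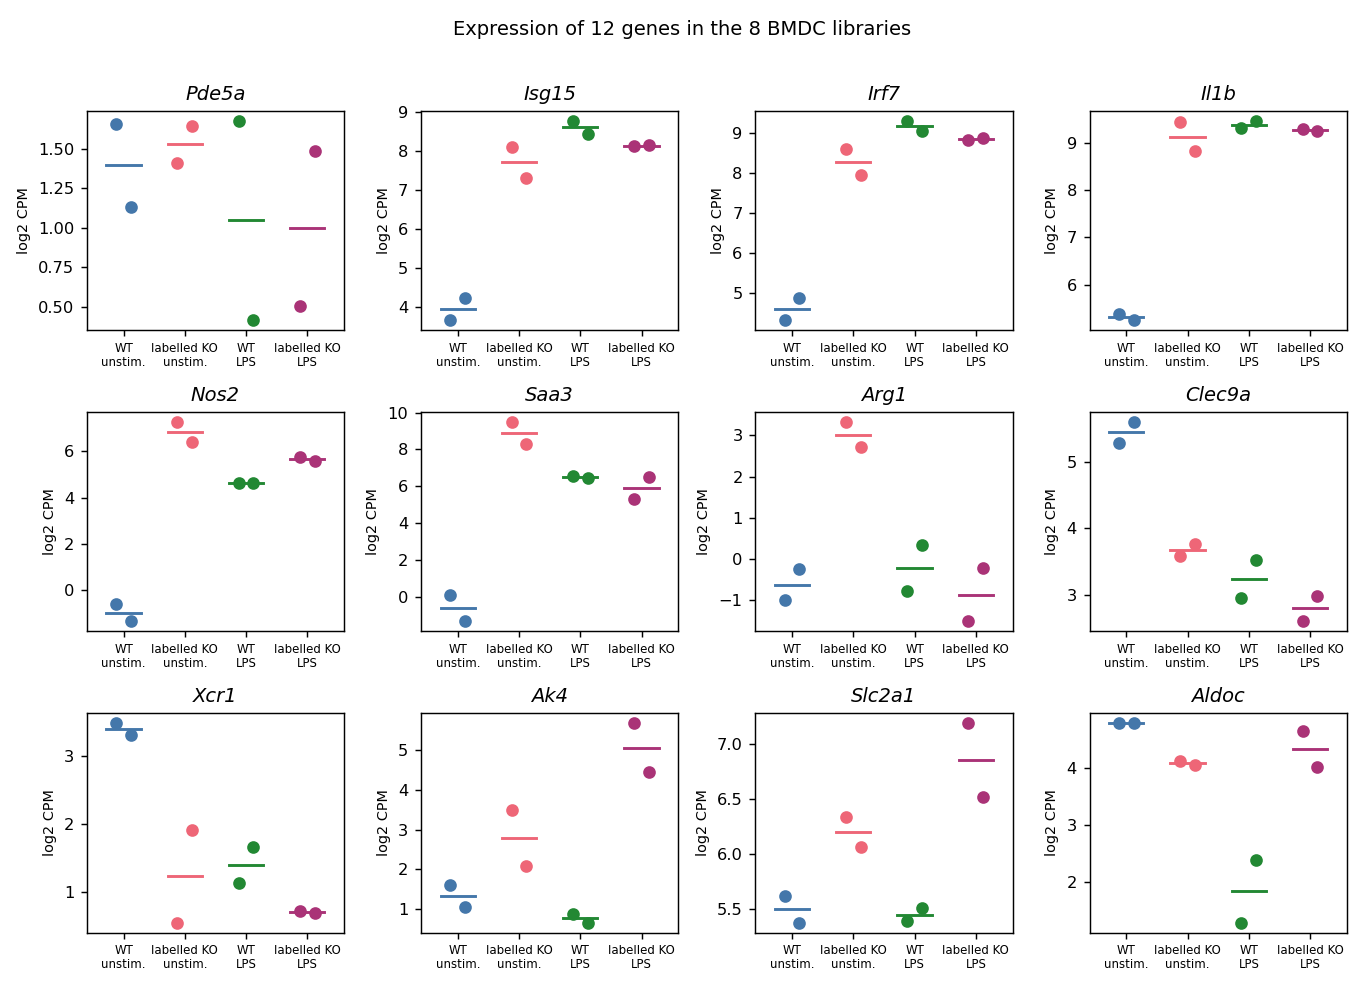
Log2 CPM of 12 genes in the 8 BMDC libraries, grouped by genotype label and stimulation; points are libraries and bars are means of 2. Pde5a is low in all groups, whereas Nos2 is at 0.417 CPM in WT unstimulated libraries, 119 CPM in libraries labelled unstimulated knockout, 24.5 CPM in WT LPS and 50.8 CPM in libraries labelled LPS knockout.

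Under LPS, the lists of hypoxia and glycolysis genes lay higher in the libraries labelled knockout than in WT at a preset correlation between genes, but no single gene passed. Both list calls were lost with an estimated correlation (adjusted p = 0.279 for each) and neither passed with fry (adjusted p = 0.197 for each). Aldoc, a glycolytic aldolase, was at 3.72 ± 1.99 CPM in WT and 20.5 ± 6.26 CPM in the libraries labelled knockout (log2 fold change 2.46, SE 0.338), and the mitochondrial kinase Ak4, a hypoxia target, at 1.59 ± 0.182 and 36.4 ± 20.8 CPM (4.51, SE 0.653). The glucose transporter Slc2a1 was at 43.6 ± 2.54 and 119 ± 38.5 CPM (1.45, SE 0.215), and the collagen-modifying enzyme Plod2 at 5.0 ± 0.181 and 18.4 ± 6.42 CPM (1.88, SE 0.252). In edgeR each of these had an adjusted p of 0.166, the smallest of the comparison, which gave 0 genes. An unadjusted p under 0.05 was reached by 1330 genes, DESeq2 called 150 genes (113 higher and 37 lower) and limma-voom 0.

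The hypoxia list had 0 of 23 genes passing alone and 17 higher when adjusted over the list alone. Its median was +1.17 (camera adjusted p = 8.45e-34, adjusted p = 0.279 with an estimated correlation). Glycolysis had 0 of 20 passing, with 15 higher and 1 lower when adjusted over the list alone. The median was +1.19 (adjusted p = 4.46e-33, adjusted p = 0.279 with an estimated correlation). Lysosome and phagocytosis genes had a median of -0.47 (28 genes, 0 passing, 0 when adjusted over the list alone, adjusted p = 1.26e-09, adjusted p = 0.398 with an estimated correlation). Chemokine genes had one of -0.63 (21 genes, adjusted p = 0.000369) and lipid handling genes one of -0.43 (22 genes, adjusted p = 0.000369), with Lipa, the lysosomal lipase, at -1.16. Costimulation genes lay at +0.36 (12 genes, adjusted p = 0.000369), with 4 higher when adjusted over the list alone, among them Tnfsf4 (+0.77, adjusted p = 0.277) and Cd86 (+0.54, adjusted p = 0.276). For these 3 lists the adjusted p was 0.398 with an estimated correlation, and 0 of their genes passed.

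Monocyte and macrophage genes had a median of -0.61 (24 genes, adjusted p = 0.00136, adjusted p = 0.484 with an estimated correlation), with the lysozyme gene Lyz2 at 975 ± 219 CPM in WT and 544 ± 228 CPM in the libraries labelled knockout. The type I interferon list had a median of -0.35 (35 genes, adjusted p = 2.02e-05, adjusted p = 0.777 with an estimated correlation), MHC class I -0.155 (20 genes, adjusted p = 0.00384, adjusted p = 0.545 with an estimated correlation), Toll-like receptor sensing -0.15 (19 genes, adjusted p = 0.0132, adjusted p = 0.398 with an estimated correlation), NK genes +0.75 (8 genes, adjusted p = 0.0244, adjusted p = 0.398 with an estimated correlation) and neutrophil genes +0.21 (14 genes, adjusted p = 0.0457, adjusted p = 0.71 with an estimated correlation). In all of these lists 0 genes passed, also when adjusted over the list alone. Without WT LPS replicate 1 the calls of the interferon, sensing, NK and neutrophil lists ended (adjusted p = 0.569, 0.132, 0.0985 and 0.222), the interferon median then being -0.04, without WT LPS replicate 2 that of MHC class I (0.0584), and without the library labelled LPS knockout replicate 1 those of the macrophage, MHC class I, NK and neutrophil lists (0.297, 0.076, 0.076 and 0.0921). Without the library labelled LPS knockout replicate 2 the count of genes was 60, and the sensing, NK and neutrophil lists lost their calls (0.0601, 0.0537 and 0.0705), as did the neutrophil list under library size alone or the filter of 10 CPM (0.0711 and 0.252).

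In the libraries labelled knockout, LPS against no stimulation gave 0 genes in edgeR, with a smallest adjusted p of 0.0502. Arg1 stood at 8.17 ± 2.47 CPM unstimulated and 0.494 ± 0.362 CPM with LPS (log2 fold change -4.04, SE 0.569, adjusted p = 0.0502), and the interferon-gamma-induced Gbp4 at 69.5 ± 15 and 146 ± 18.3 CPM (1.07, SE 0.149, adjusted p = 0.0502). Il18bp, the inhibitor of IL-18, was at +0.98 (SE 0.125) and the C-type lectin Clec4d at -0.995 (SE 0.118), with the same adjusted p. An unadjusted p under 0.05 was reached by 2800 genes and an adjusted p under 0.06 by 29. DESeq2 called 793 genes (352 higher and 441 lower) and limma-voom 0. Lists that lay higher with LPS included interferon-gamma (median +0.64, 24 genes, 12 higher and 1 lower when adjusted over the list alone, adjusted p = 2.11e-10), hypoxia (+0.69, 23 genes, 12 higher when adjusted over the list alone, adjusted p = 8.52e-09), type I interferon (+0.53, 35 genes, 0 when adjusted over the list alone, adjusted p = 1.21e-08) and glycolysis (+0.68, 20 genes, 13 higher and 2 lower when adjusted over the list alone, adjusted p = 9.67e-08). On the lower side were monocyte and macrophage genes (-0.71, 24 genes, 3 lower when adjusted over the list alone, adjusted p = 1.37e-05), cDC1 genes (-0.81, 16 genes, 7 lower when adjusted over the list alone, adjusted p = 0.000136) and lysosome genes (-0.51, 28 genes, 7 lower when adjusted over the list alone, adjusted p = 0.000518). Each of the 12 lists that passed had an adjusted p of at least 0.568 with an estimated correlation. Without the library labelled unstimulated knockout replicate 1 the comparison gave 599 genes and without the library labelled LPS knockout replicate 2 it gave 11, and without LPS replicate 1 of that label the lysosome list lost its call (adjusted p = 0.0567).

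Across all tested genes, the LPS responses in libraries labelled knockout and in WT had a Pearson correlation of 0.505 and a slope of 0.336 by total least squares, and 72.7% of genes had the same sign. A test of the difference between both responses (the interaction) gave 585 genes, 74 with a higher and 511 with a lower response in the libraries labelled knockout. Saa3 had an interaction log2 fold change of -10.17 (SE 0.933, edgeR adjusted p = 0.00668), Nos2 one of -7.08 (SE 0.530, adjusted p = 0.00586), Fpr2 one of -7.01 (SE 0.691, adjusted p = 0.00652) and Il1b one of -3.97 (SE 0.266, adjusted p = 0.00291). In these genes the unstimulated libraries labelled knockout already stood far above WT before LPS. On the higher side, Aldoc (3.17, SE 0.449, adjusted p = 0.0129) and the glucose transporter Slc2a3 (2.42, SE 0.481, adjusted p = 0.0369) responded more in the libraries labelled knockout. Of 35 type I interferon genes, 31 had a lower response and 0 a higher one, with 34 lower when adjusted over the list alone. The median was -2.77 (camera adjusted p = 2.92e-61, adjusted p = 0.201 with an estimated correlation). Interferon-gamma genes counted 17 lower and 0 higher of 24, with 20 and 1 when adjusted over the list alone. Their median was -2.31 (adjusted p = 8.63e-34, adjusted p = 0.157 with an estimated correlation). NF-kB genes counted 6 lower and 0 higher of 28, with 17 lower when adjusted over the list alone. The median was -0.835 (adjusted p = 3.04e-20, adjusted p = 0.157 with an estimated correlation). The count was 1076 without the library labelled unstimulated knockout replicate 2, 194 without replicate 1 of that group, 218 without WT unstimulated replicate 2, 108 and 241 without WT LPS replicate 1 and 2, and 45 without the library labelled LPS knockout replicate 1. Slc2a3 and Aldoc lost their calls without the library labelled unstimulated knockout replicate 1 (adjusted p = 0.164 and 0.0593) and LPS knockout replicate 1 (0.0634 and 0.0551), and Slc2a3 also without each of 4 further libraries (highest adjusted p 0.144), without a filter (0.104) and with a replicate block (0.0644), while library size alone moved the median of all genes by 0.126.

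Averaged over both stimulation states, 1446 genes differed between knockout-labelled and WT libraries, 1021 higher and 425 lower, of which 302 and 46 differed by more than 2-fold. The knockout label gave 2357 genes without stimulation and 0 under LPS, so a call in the average does not show a difference in both states. Glycolysis genes were higher in 13 of 20 cases and lower in 0, with 17 and 1 when adjusted over the list alone. The median was +0.61 (camera adjusted p = 3.04e-10, adjusted p = 0.277 with an estimated correlation). Hypoxia genes were higher in 15 of 23 cases and lower in 0, with 18 and 1 when adjusted over the list alone. Their median was +0.955 (adjusted p = 4.16e-17, adjusted p = 0.277 with an estimated correlation). Cxcr5, the receptor for the follicle chemokine CXCL13, rose (2.01, SE 0.130, edgeR adjusted p = 0.00155), as did Gzmb, the cytotoxic protease granzyme B (2.04, SE 0.320, adjusted p = 0.00918), and Slc16a3, a lactate exporter (1.70, SE 0.249, adjusted p = 0.0126). Mgarp, a mitochondrial protein, had the highest value (5.10, SE 0.807, adjusted p = 0.0135) but stood at 1.20 ± 1.21 CPM in the unstimulated libraries labelled knockout. Tnf, the cytokine TNF, fell (-0.85, SE 0.142, adjusted p = 0.0118), as did Clec9a (-1.12, SE 0.159, adjusted p = 0.00649) and Tlr3 (-1.13, SE 0.193, adjusted p = 0.0136). Type I interferon genes counted 26 higher and 0 lower of 35, with 32 higher when adjusted over the list alone. The median was +0.995 (adjusted p = 2.29e-25, adjusted p = 0.277 with an estimated correlation). This average joined opposite directions, with medians of +2.27 without stimulation and -0.35 under LPS. Costimulation genes counted 7 higher and 0 lower of 12, with 8 and 1 when adjusted over the list alone. The median was +0.71 (adjusted p = 8.82e-07, adjusted p = 0.277 with an estimated correlation). Lysosome genes counted 1 higher and 6 lower of 28, with 2 and 10 when adjusted over the list alone. Their median was -0.29 (adjusted p = 0.000374, adjusted p = 0.519 with an estimated correlation). Leaving out 1 library gave between 378 genes (without WT LPS replicate 1) and 2297 (without the library labelled unstimulated knockout replicate 2), with 624 without WT unstimulated replicate 2, 483 without the library labelled unstimulated knockout replicate 1, 388 without WT LPS replicate 2, and 446 and 687 without the libraries labelled LPS knockout replicate 1 and 2. Mgarp lost its call without WT LPS replicate 1 or 2 (adjusted p = 0.0544 and 0.0524), and Slc16a3 without a filter (0.0503).

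**Figure D4:**
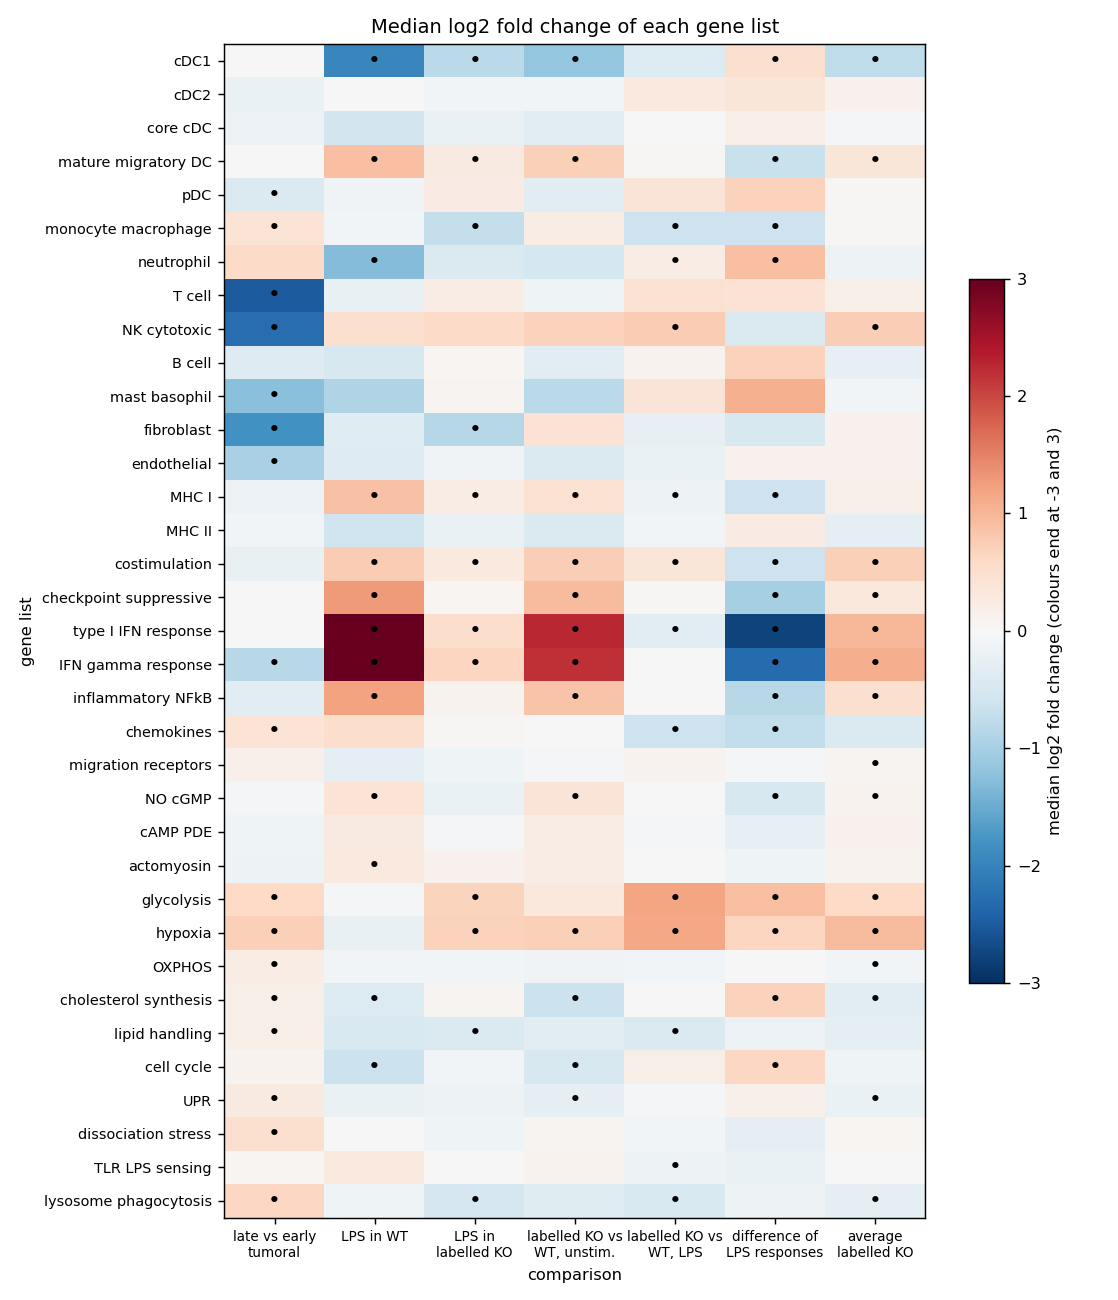
Median log2 fold change of 35 gene lists in 7 comparisons, as a heat map whose colors end at -3 and 3; dots mark lists whose camera adjusted p was under 0.05 with the preset correlation, none of which kept its call with an estimated correlation. Type I interferon genes stand at 3.3 for LPS in WT, 2.27 for the knockout label in unstimulated cells and -2.77 for the difference of LPS responses.

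To ask whether the tumoral change resembled LPS activation or the effect of the knockout label, the BMDC gene sets were tested in the late against early comparison. The 2470 genes raised by LPS in WT BMDCs had a median of -0.08 (camera adjusted p = 0.074) and the 2239 genes lowered by LPS one of +0.10 (adjusted p = 0.056). The 419 genes lower in knockout-labelled BMDCs on average lay higher in late tumoral DCs (median +0.22, adjusted p = 7.81e-05, adjusted p = 0.68 with an estimated correlation), whereas the 969 genes higher in knockout-labelled BMDCs did not pass (median -0.16, adjusted p = 0.0554). With sets limited to an adjusted p under 0.01 and more than 2-fold, the 696 genes raised by LPS had a median of -0.22 (adjusted p = 0.00242, adjusted p = 0.807 with an estimated correlation) and the 116 genes higher with the knockout label one of -0.38 (adjusted p = 0.00494, adjusted p = 0.807 with an estimated correlation). The 577 genes lowered by LPS did not pass (median +0.05, camera adjusted p = 0.734). The set lower with the knockout label held only 2 genes at these limits and was not tested. At most 1 gene was called in both experiments in any direction (Fisher's exact test, smallest p = 0.135). Late against early gave only 3 calls, 0 of them higher, so few shared calls were possible and this test cannot decide the question.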

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

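The tests of explanations in this part were chosen after the results were seen, whereas the interaction, its alternatives and the exchange of libraries between genotype labels were chosen before. The response to LPS differed between genotype labels in 585 genes and 16 gene lists. With an estimated correlation 0 of these lists passed (smallest adjusted p 0.157). Among genes, the interaction log2 fold change was 3.17 for Aldoc, 2.51 for Zfp395, 2.42 for Slc2a3, 2.29 for Mthfd1l, 2.29 for Gpr34, 2.26 for Epm2a, 2.22 for Impa2 and 2.16 for Ltf. On the lower side it was -10.17 for Saa3, -7.08 for Nos2, -7.01 for Fpr2, -6.98 for Slfn4, -6.81 for Olfr56, -6.66 for Ifi206, -6.38 for Slfn1 and -6.3 for Gstt1. In these 8 lower genes the unstimulated libraries labelled knockout already lay above WT. With a replicate block Slc2a3, Gpr34, Epm2a and Impa2 lost their calls (edgeR adjusted p = 0.0644, 0.057, 0.0553 and 0.0558). Gpr34 and Epm2a lost theirs with limma-voom (adjusted p = 0.0671 and 0.0522). In edgeR Gpr34 lost its call with the filter of 10 CPM (0.0535), and Slc2a3 and Impa2 without a filter (0.104 and 0.0508). The calls of all 8 higher genes ended without the library labelled LPS knockout replicate 1 (adjusted p = 0.0551, 0.0634, 0.0634, 0.0551, 0.207, 0.165, 0.0634 and 0.135, in the order above) and without the library labelled unstimulated knockout replicate 1 (0.0593, 0.08, 0.164, 0.125, 0.129, 0.141, 0.139 and 0.104). Those of the 7 other than Aldoc ended without WT LPS replicate 1 (0.0703, 0.144, 0.112, 0.139, 0.151, 0.127 and 0.112) and without WT unstimulated replicate 2 (0.0518, 0.108, 0.0836, 0.0951, 0.0998, 0.0989 and 0.0877). Slc2a3, Mthfd1l, Gpr34, Epm2a and Impa2 lost theirs without WT LPS replicate 2 (0.101, 0.08, 0.129, 0.0694 and 0.0978), Gpr34 and Epm2a without WT unstimulated replicate 1 (0.0718 and 0.0648) and Slc2a3 without the library labelled unstimulated knockout replicate 2 (0.0643). On the lower side Slfn4, Olfr56 and Gstt1 lost theirs without the library labelled LPS knockout replicate 1 (0.0551, 0.0501 and 0.0551).

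Among lists, the median interaction was -2.77 for type I interferon, -2.31 for interferon-gamma, -0.99 for checkpoint, -0.835 for NF-kB, -0.74 for chemokine, -0.66 for mature DC, -0.625 for monocyte and macrophage, -0.62 for MHC class I, -0.61 for costimulation and -0.475 for nitric oxide and cGMP genes. It was 0.905 for neutrophil, 0.90 for glycolysis, 0.69 for cholesterol synthesis, 0.65 for hypoxia, 0.63 for cell cycle and 0.48 for cDC1 genes. Against the direction of the hypoxia median, 0 of its 23 genes passed higher and 4 passed lower, with 9 and 4 when adjusted over the list alone. Of 16 cDC1 genes 0 passed higher and 1 lower, with 1 and 1 when adjusted over the list alone. With an estimated correlation the adjusted p was at least 0.157 for the lower and at least 0.441 for the higher lists. Library size alone ended the calls of hypoxia and cDC1 (adjusted p = 0.0754 and 0.0772), upper-quartile scaling that of cDC1 (0.0505) and the filter of 10 CPM those of cDC1, hypoxia and costimulation (0.0618, 0.0618 and 0.071). Hypoxia also lost its call without WT unstimulated replicate 1 (0.156), the library labelled unstimulated knockout replicate 2 (0.62), WT LPS replicate 1 or 2 (0.0642 and 0.0529) and the library labelled LPS knockout replicate 1 (0.116). Costimulation lost it without WT unstimulated replicate 1 (0.156), the library labelled unstimulated knockout replicate 1 (0.0892), WT LPS replicate 2 (0.0845) and the library labelled LPS knockout replicate 2 (0.203), and cDC1 without the library labelled unstimulated knockout replicate 1 (0.156), WT LPS replicate 1 (0.136) and the library labelled LPS knockout replicate 2 (0.0727). The chemokine call ended without WT unstimulated replicate 1 (0.0646), the neutrophil call without WT unstimulated replicate 2 (0.0728) and the cell cycle call without WT LPS replicate 1 (0.136) or the library labelled LPS knockout replicate 1 (0.0623).

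High LPS-response genes in the libraries labelled unstimulated knockout could come from an exchange of labels with an LPS library among the 8. With each WT LPS library placed along a WT response called and drawn without it, the lowest position of the 4 libraries labelled LPS was 0.836 (WT LPS replicate 2), so this was argued against. Contact of these cultures with LPS or another activator, or a wrong label from outside the 8, stays open, since the mean position of the 2 libraries was 0.71 and the knockout itself would give the same value. The knockout itself also stays open, because the Pde5a log2 fold change of 0.00214 leaves the genotype unseen in the counts.

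The lower T cell and NK genes in late tumoral libraries could come from lymphocytes among the sorted cells, fewer in the late samples. Both late libraries lay below both early ones in 28 of 29 tested members (96.6%, against 16.7% by chance for 2 against 2), which restates that these lists were lower and leaves this open. Fibroblast, mast cell and endothelial lists were lower too (medians -1.82, -1.26 and -0.96), so a lower share of several other cell types also stays open. Only a like fall of every other type was argued against, by a neutrophil list that did not pass (adjusted p = 0.133) but whose median of -0.538 to 2.04 without 1 library lay above the T cell range of -3.05 to -2.03 by more than the SD of either list (1.08 and 0.961). The Zbtb46 reporter sort is the step at which such cells could enter, and whether the stage or the sort changed their share was not tested.

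Higher hypoxia genes in libraries labelled LPS knockout could come from 1 library alone, but the list median stayed between 0.783 and 1.48 over the fits without 1 library, so this was argued against. Glycolysis stayed between 0.806 and 1.5. Oxygen or density differing between cultures stays open, since the 2 libraries labelled LPS knockout differed by 0.565 in mean log2 CPM of the list and the 2 WT LPS libraries by 0.115, at group means of 6.18 and 4.88. The design gives no measure of either.

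Exchanging libraries between genotype labels within each stimulation state gave 18 splits, too few for a share under 0.05. The real split gave 1446 genes and the highest other split 689, so of the 18 splits only the real split itself reached that count. Every other split with calls kept the unstimulated libraries grouped by genotype label and exchanged only LPS libraries, so 689 is not a level for unrelated groupings. Each split that mixed the unstimulated libraries between labels gave 0 genes.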

How the results depend on the processing

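The tests without the T cell and NK genes, without both libraries labelled unstimulated knockout, with thinned libraries and with identical symbols merged were chosen after the result was seen, and the others before. Of 212 called gene values, 96 kept direction and call in every alternative in which they were tested, 116 lost the call in at least 1 and 0 reversed; 17 were not tested in at least 1. Stricter thresholds ended 110 of these calls, leaving out 1 library 98, another filter 30, DESeq2 or limma-voom 12, a replicate block 10 and another scaling 6. All 99 list results lost the call with an estimated correlation, which passed 0 lists in any comparison and so does not tell them apart. Without each library the direction of the camera test stayed in all 99 and 67 kept the call, but the median of the chemokine list for late against early changed sign without early replicate 1 (-0.02). Another filter ended 11 list calls and another scaling 4. Where counts moved, the cause was not tested.

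For late against early, where the count was 3, DESeq2 size factors gave 0 genes, upper-quartile scaling 45, library size 28, no filter 689, the 10 CPM filter 0, DESeq2 311, limma-voom 0, an adjusted p under 0.01 0 and the fit without T cell and NK genes 0. Leaving out 1 library gave 0 to 1088. For LPS in WT, against 4910, the 2-fold limit gave 1921, an adjusted p under 0.01 2564 and leaving out 1 library 2632 to 4063. For LPS in libraries labelled knockout, against 0, DESeq2 size factors gave 22, upper-quartile scaling 21, library size 24, no filter 587, DESeq2 793, merged symbols 20 and leaving out 1 library 0 to 599.

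For the knockout label without stimulation, against 2357, the 2-fold limit gave 820, an adjusted p under 0.01 779, the 4 libraries alone 1036 and leaving out 1 library 576 to 2735. Under LPS, against 0, no filter gave 56, DESeq2 150 and leaving out 1 library 0 to 60. For the interaction, against 585, no filter gave 948, DESeq2 1082, an adjusted p under 0.01 75 and leaving out 1 library 45 to 1076. For the average, against 1446, the 2-fold limit gave 348, an adjusted p under 0.01 238 and leaving out 1 library 378 to 2297.

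A replicate block, pairing libraries by number, gave 173 genes for late against early, 321 for LPS in libraries labelled knockout and 2 for the knockout label under LPS. Deviations of equally numbered BMDC libraries correlated between -0.2 and 0.275, so a pairing of the samples by number was not shown.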

Other observations

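The contrasts with the LPS libraries in this part were chosen after the result was seen. The libraries labelled unstimulated knockout were set against the 4 LPS libraries, which gave 155 genes, 108 higher and 47 lower in edgeR. Among the higher genes were 4 chosen after their values were seen: Arg1, which encodes arginase, by 3.68 (SE 0.427, adjusted p = 0.0218), Saa3, an acute-phase protein, by 2.77 (SE 0.398, adjusted p = 0.0403), Nos2 by 1.75 (SE 0.217, adjusted p = 0.029) and Hp, which encodes the hemoglobin scavenger haptoglobin, by 1.55 (SE 0.216, adjusted p = 0.03). Spic, a transcription factor of iron-recycling macrophages and chosen in the same way, was lower by 0.85 (adjusted p = 0.0218). Against the 2 WT LPS libraries, an equal-sized contrast, only Spic differed (-1.08, adjusted p = 0.0169), which made 1 gene.

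In the tumoral DCs, Arg1 and Nos2, which compete for arginine, had log2 fold changes of 1.72 (SE 0.626) and 1.23 (SE 0.523) from early to late, and neither passed in edgeR (adjusted p = 0.426 and 0.469). Arg1 stood at 294 ± 244 CPM early and 966 ± 24.9 CPM late, and Nos2 at 130 ± 80.2 and 303 ± 136 CPM.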
